A study of Mus musculus with 12 samples.

How the data were processed

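Gene expression was measured on 12 Affymetrix Mouse Gene 1.0 ST arrays in 5 groups of mouse cells. Per the labels, the groups were cultured astrocytes (3 arrays), cells sorted at day 6 of reprogramming (3), neural stem cells (2), induced pluripotent stem cells (iPSCs) made from astrocytes (2) and iPSCs made from mouse embryonic fibroblasts, MEFs (2). Total RNA was amplified and labelled with the GeneChip WT PLUS kit. The submitters' design text calls the replicates biological, and the labels do not say whether each came from its own animals or culture, so the p values measure the spread between these samples, which may be in part technical.

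The deposited values are probe set intensities from robust multi-array averaging (RMA), per the submitters' processing notes, with background correction and normalization between arrays. The RMA software version is not given in the sources used here. A log2 scale was planned for, and the values turned out to be linear. They ran from 20.2 to 15436 intensity units, with array medians between 97.9 and 104.9, and log2 was taken before every step. The absence of values under 20.2 leaves open that a constant was added before deposit, which would shrink log2 differences of dim genes. Genome positions were not used.

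Of 28853 probe sets, 21789 carry exactly 1 gene symbol, 1621 carry several genes and 5443 carry none. For each of 19938 genes, the single-symbol probe set with the highest mean over the 12 arrays was kept, and 999 genes had more than 1 such probe set. No filter on dim probe sets was applied in the reported values.

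Differences between groups were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 12 arrays (7 residual degrees of freedom, 10.9 with the prior). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. Errors of fold changes are limma standard errors (SE), and errors of levels are standard deviations (SD) over the arrays of a group. In simulated data with the same layout, run once for each of the 6 comparisons with 50 changed genes at each size, 96% to 100% of genes changed by 1.25 to 3 on the log2 scale were recovered. There was 1 false call between the iPSC groups and 0 in each other comparison. The simulated noise was normal and independent between genes, and every change lay past the fold limit. These rates hold for such data only and do not give the error rates of the real arrays.

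Lists were tested in 6 comparisons, day 6 cells were also compared gene by gene with MEF iPSCs, and genes set apart in the day 6 cells were those called in the same direction against each of the 4 other groups. The position of the day 6 cells between astrocytes and a reference was given by the share of reference genes lying toward it and by the median ratio of the 2 differences. Because the astrocyte arrays enter both differences, these values and the correlations were also computed by cross-fit. There, genes and the reference difference came from 2 astrocyte arrays, and the day 6 difference was taken against the remaining one. Unchanged groups were also simulated against the same astrocyte arrays in 100 draws with seed 1. Distances between groups are root mean square log2 differences of group means with the part due to the spread between arrays subtracted.

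Gene lists for cell types, pathways and possible other cells were fixed before the data were examined. Of 524 list entries, 482 were matched to a single-symbol probe set, 28 of the 29 lists had at least 3 measured members, and these were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. The test was repeated with a correlation estimated from the residuals. The genes named in the text follow a rule of the same date. It takes the called genes with the highest and lowest fold changes and arrays that did not overlap between the groups (8 each way in the first 4 comparisons, 5 in the other 2, 6 for genes set apart). It adds up to 4 members of each list with the largest absolute fold change, the 4 delivered factors with Sox1, and Xist with Y-linked genes. Predicted genes, clone names, olfactory and vomeronasal receptors and ribosomal pseudogenes were left out.

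The alternatives were the mean of a gene's probe sets, all probe sets, dim genes left out (12592 kept, above the array's median in at least 2 arrays), cyclic loess, centring of arrays on the median, only the 2 groups compared, eBayes with trend and robust settings, array weights, an adjusted p under 0.01, no fold limit, the replicate number as a block, and leaving out each array in turn. Subtracting 16 before log2, a batch term for replicate 1 arrays, the division of neural stem cell genes by their change in iPSCs, and the position between neural stem cells and iPSCs were added after seeing the data. All deposited arrays were used. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.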

Results

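Astrocytes were cultured from the cortex of mice at postnatal day 3 in serum-containing medium and sorted for cells negative for a green fluorescent protein (GFP) placed in the Sox1 gene, a transcription factor gene of the early neural plate and neural stem cells. Retroviruses carrying Pou5f1 (Oct4), Klf4, Sox2 and Myc were then added, and GFP-positive cells were sorted at day 6, in embryonic stem cell medium with leukaemia inhibitory factor (LIF). These sorted cells are called day 6 cells here. Neural stem cells came from the telencephalon of embryos of day 12.5 to 14.5 and grew in serum-free medium with growth factors. The 2 iPSC groups grew on growth-arrested MEF feeder cells with LIF, and the MEF line carries a Nanog-GFP reporter in place of Sox1-GFP. There were 3 arrays each of astrocytes and day 6 cells and 2 of each other group. The number of arrays limits the precision, and medium, age and reporter go with the groups. Between arrays of the same group, Pearson's r across probe sets was 0.992 to 0.996.

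The comparison of day 6 cells with astrocytes asks which genes differed between the sorted cells and the population that received the factors. The 12 arrays hold no unsorted or GFP-negative cells of day 6. Falls and rises are therefore differences between groups, in which change within cells and selection by the sort cannot be told apart. Astrocyte genes were far lower in the day 6 cells. Gfap, the intermediate filament of astrocytes, stood at a log2 intensity of 12.32 ± 0.29 (SD, n = 3) in astrocytes and 6.37 ± 0.04 (n = 3) in day 6 cells, a log2 fold change of -5.95 ± 0.12 (SE). Fabp7, a fatty acid binding protein of radial glia, fell by 5.69 ± 0.13 on the log2 scale. At the same time Nr0b1, a nuclear receptor of the pluripotency network, rose by 5.11 ± 0.12, and Epcam, an epithelial adhesion molecule, by 3.04 ± 0.07. The largest adjusted p of these 4 genes was 5.5e-11. In all, 1346 of 19938 genes were higher and 2014 lower in day 6 cells, 3360 together.

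Of the 27 measured astrocyte markers, 22 fell and 0 rose, with a median log2 fold change of -2.90 (camera adjusted p = 1.49e-14, and adjusted p = 0.0725 with an estimated correlation). Besides Gfap, the markers with the largest changes were Sparcl1, an extracellular matrix protein (-5.42 ± 0.12), Atp1b2, a sodium pump subunit (-5.35 ± 0.11), and Slc1a3, a glutamate transporter (-5.34 ± 0.11). Neural stem and progenitor genes went both ways, 5 higher and 10 lower of 28, with a median of -0.45 (adjusted p = 0.0438, and adjusted p = 0.532 with an estimated correlation). Olig2 and Olig1, transcription factors of oligodendrocyte and neural progenitors, fell by 4.29 ± 0.15 and 4.06 ± 0.16, and Nr2e1, an orphan nuclear receptor of neural stem cells, by 3.33 ± 0.10. The progenitor call was lost without dim genes (adjusted p = 0.200), with cyclic loess (0.136), without astrocytes replicate 1 (0.0611) and without either neural stem cell array (0.0567). Markers of microglia, which astrocyte cultures can hold, had 1 member higher and 2 lower of 20 (median -0.45, adjusted p = 0.0105, adjusted p = 0.596 with an estimated correlation and 0.402 without dim genes). Lyz2, the macrophage lysozyme, fell by 2.54 ± 0.29, while Laptm5, a lysosomal membrane protein of blood cells, rose by 1.54 ± 0.21.

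Interferon response genes were lower, 12 of 17 with 0 higher, and the median was -1.67 (adjusted p = 1.22e-06, and adjusted p = 0.234 with an estimated correlation). Ifit3 and Ifit1, interferon-induced antiviral proteins, fell by 3.94 ± 0.11 and 3.15 ± 0.14. TGF-beta and BMP targets fell in 11 of 14 members with 0 higher (median -1.71, adjusted p = 1.58e-05, and adjusted p = 0.165 with an estimated correlation), among them the transcriptional inhibitors Id4 (-2.80 ± 0.13) and Id3 (-2.47 ± 0.21). In the mesenchymal and matrix list 14 of 26 members fell and 1 rose (median -1.13, adjusted p = 1.32e-05, and adjusted p = 0.50 with an estimated correlation). Tagln and Acta2, contractile proteins of smooth muscle and myofibroblasts, fell by 5.09 ± 0.10 and 3.49 ± 0.15. Reactive and inflammatory genes had 2 members higher and 6 lower of 17 (median -0.34, adjusted p = 0.0121, adjusted p = 0.532 with an estimated correlation and 0.0672 without dim genes), with Cp, the copper carrier ceruloplasmin, down by 5.66 on the log2 scale (-5.66 ± 0.09). Fibroblast and feeder genes had 6 lower and 0 higher of 18 (median -0.49, adjusted p = 0.0438, and adjusted p = 0.754 with an estimated correlation), led by Ogn, a matrix proteoglycan (-7.21 ± 0.12). That call was lost without dim genes (adjusted p = 0.138), with cyclic loess (0.124), without astrocytes replicate 3 (0.0777, median -0.30), without day 6 replicate 1 (0.0516) and without either neural stem cell array (0.0567).

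Proliferation genes moved the other way. Of 29 cell cycle genes, 27 rose and 0 fell, by a median of 1.78 (adjusted p = 5.04e-14, and adjusted p = 0.415 with an estimated correlation), with the replication helicase subunits Mcm5 (2.29 ± 0.10) and Mcm7 (2.22 ± 0.14) at the top. DNA methylation and Polycomb genes rose in 11 of 17 with 0 lower (median 1.39, adjusted p = 1.32e-05, and adjusted p = 0.234 with an estimated correlation), including Jarid2, a Polycomb cofactor (2.55 ± 0.10), and Uhrf1, a partner of maintenance methylation (2.17 ± 0.12). Epithelial genes rose in 7 of 19 with 0 lower (median 0.60, adjusted p = 8.41e-06, and adjusted p = 0.234 with an estimated correlation), and Cdh1, E-cadherin, rose by 2.41 ± 0.10. The pluripotency list had 11 members higher and 2 lower of 30 (median 0.41, adjusted p = 0.000194, and adjusted p = 0.50 with an estimated correlation). L1td1, an RNA-binding protein, rose by 3.26 ± 0.13 and Sall4, a zinc finger factor, by 2.78 ± 0.12. Counts adjusted over the list alone were equal to those over all genes in each of the 28 lists.

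The delivered factors were not uniformly high on the arrays. Pou5f1 was higher in day 6 cells than in astrocytes by 1.86 ± 0.16 (adjusted p = 9.8e-07), at 7.49 ± 0.14 (SD, n = 3) against 11.95 ± 0.01 (n = 2) in astrocyte iPSCs. Sox2 was lower than in astrocytes by 2.50 on the log2 scale (-2.50 ± 0.07, adjusted p = 2.1e-10), with levels of 8.69 ± 0.11 in day 6 cells and 11.19 ± 0.08 in astrocytes. Myc fell by 1.18 ± 0.14, and Klf4 was not called, at -0.75 ± 0.14. Whether these probe sets detect retroviral as well as endogenous transcripts was not checked, so the levels may not give the total RNA of each factor. Sox1 itself, the gene behind the sort, was not called, at 0.27 ± 0.09 (adjusted p = 0.021), with levels of 8.13 ± 0.14 in GFP-negative astrocytes and 8.4 ± 0.13 in GFP-positive day 6 cells.

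**Figure D1:**
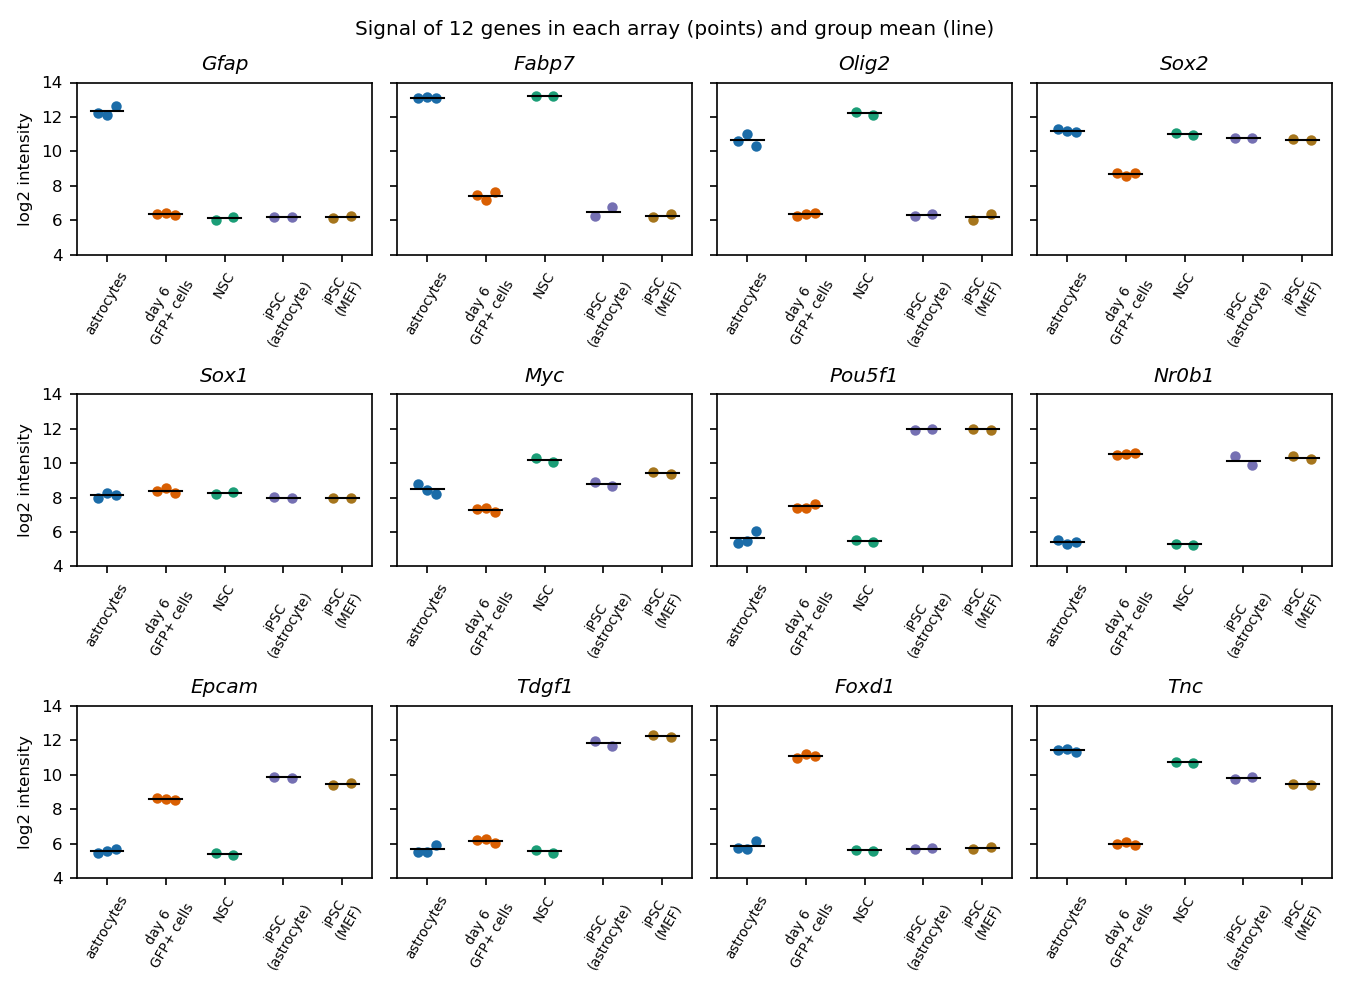
Log2 intensity (vertical axis) of 12 genes in each of the 12 arrays, grouped by cell type, with points for arrays and lines for group means. Foxd1 lies at 11.08 in day 6 cells and between 5.62 and 5.87 in the other groups, and Fabp7 lies at 7.43 in day 6 cells against 13.11 in astrocytes and 13.19 in neural stem cells.

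The lists that did not pass in this comparison were neuron (2 higher and 3 lower of 20), oligodendrocyte lineage (3 and 1 of 15), endothelial and pericyte (1 and 1 of 16), glycolysis (2 and 0 of 12), imprinted genes (1 and 3 of 16), forebrain regional genes (0 and 1 of 13), Hox (0 and 0 of 18), other germ layers (0 and 1 of 19), Notch (1 and 5 of 14), FGF and ERK feedback (0 and 2 of 14), LIF and STAT3 targets (1 and 5 of 14), cholesterol synthesis (1 and 1 of 14), cell cycle inhibitors and p53 targets (1 and 4 of 14), germline and 2-cell genes (0 and 0 of 11), delivered factors (1 and 2 of 4) and the sex check (0 and 0 of 4). Single members of these lists changed strongly all the same. Nefl, a neurofilament subunit, rose by 5.14 ± 0.10, and Rtn1 and Map2, proteins of neurons and their progenitors, fell by 3.11 ± 0.10 and 2.88 ± 0.08. Hey1, a Notch target, fell by 2.81 ± 0.16, and Lhx2, a cortical transcription factor, by 2.90 ± 0.11. Cdkn2a, which encodes the inhibitors Ink4a and Arf, rose by 1.45 ± 0.09. Median and mean differed in sign for endothelial and pericyte, other germ layers, FGF and ERK feedback and cholesterol synthesis genes. Pf4 and Alas2, the measured members of the platelet and blood list, lay between 5.48 and 5.91 in every group mean.

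The comparison of day 6 cells with neural stem cells bears on how near the 2 populations were, since the series title names a state like that of neural stem cells. Many genes that mark neural stem cells were low in the day 6 cells. On the log2 scale Fabp7 was at -5.76 ± 0.14, Olig2 at -5.85 ± 0.17 and Rfx4, a transcription factor of the developing brain, at -4.12 ± 0.17. Foxd1, a forkhead factor, was higher by 5.47 ± 0.12 and Nr0b1 by 5.25 ± 0.13. The largest adjusted p of these 5 genes was 1e-08. There were 586 genes higher and 1185 lower in day 6 cells, 1771 in all. The excess of lower genes holds only for changes past the fold limit, since without it 3992 were higher and 3663 lower.

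In the neural stem and progenitor list, 14 of 28 members were lower and 1 higher (median -1.04, adjusted p = 2.68e-08, and adjusted p = 0.142 with an estimated correlation). Astrocyte markers, several of which neural stem cells share, were lower in 13 of 27 and higher in 3 (median -0.76, adjusted p = 1.22e-05, and adjusted p = 0.154 with an estimated correlation). Slc1a3 (-4.36 ± 0.12) and Sox9, a factor of glia and neural progenitors (-3.70 ± 0.13), were among them. Neuronal genes were lower in 13 of 20 and higher in 2 (median -1.77, adjusted p = 7.84e-11, and adjusted p = 0.154 with an estimated correlation). Dcx, the microtubule protein of migrating neurons (-3.90 ± 0.23), and Map2 (-4.40 ± 0.09) were lower, and Nefl was higher (3.79 ± 0.11). Forebrain regional genes were lower in 5 of 13 with 0 higher (median -0.52, adjusted p = 0.000946, and adjusted p = 0.154 with an estimated correlation), among them Lhx2 (-2.17 ± 0.12) and the interneuron factor Dlx1 (-1.85 ± 0.13).

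Cholesterol synthesis genes were lower in 9 of 14 with 0 higher (median -1.28, adjusted p = 7.84e-11, and adjusted p = 0.118 with an estimated correlation), with Lss, lanosterol synthase, at -1.93 ± 0.11 and Hmgcs1, an early enzyme of the pathway, at -1.77 ± 0.11. Imprinted genes were lower in 7 of 16 with 0 higher (median -0.85, adjusted p = 0.00212, and adjusted p = 0.154 with an estimated correlation), led by Nnat (-4.49 ± 0.17) and Mest (-3.68 ± 0.23). Notch genes were lower in 4 of 14 and higher in 1 (median -0.72, adjusted p = 0.00382, and adjusted p = 0.154 with an estimated correlation), and the ligands Dll3 and Dll1 were lower by 2.22 ± 0.14 and 2.16 ± 0.11. The Notch median was -0.46 without neural stem cell replicate 1. FGF and ERK feedback genes were lower in 5 of 14 and higher in 1 (median -0.46, adjusted p = 0.00118, and adjusted p = 0.449 with an estimated correlation), and Spry1, an inhibitor of receptor signalling, was lower by 2.62 ± 0.16. The FGF median was -0.73 without neural stem cell replicate 2. The neural stem cell medium holds FGF, and that of the day 6 cells holds LIF and serum.

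Higher groups included epithelial genes, 8 of 19 with 0 lower (median 0.62, adjusted p = 4.4e-09, and adjusted p = 0.142 with an estimated correlation), and pluripotency genes, 8 of 30 with 0 lower (median 0.46, adjusted p = 1.36e-06, and adjusted p = 0.214 with an estimated correlation). TGF-beta and BMP targets were higher in 4 of 14 (median 0.42, adjusted p = 0.0127, and adjusted p = 0.214 with an estimated correlation), and LIF and STAT3 targets in 3 of 14 with 1 lower (median 0.60, adjusted p = 0.00266, and adjusted p = 0.154 with an estimated correlation). Socs3, a feedback inhibitor of STAT3 signalling, was higher by 1.91 ± 0.21 (1.03 on its other probe set), and Myc was lower (-2.87 ± 0.15). Reactive genes were higher in 3 of 17 (median 0.17, adjusted p = 0.0277, adjusted p = 0.501 with an estimated correlation and 0.0740 without neural stem cell replicate 2), among them Osmr, the oncostatin M receptor (3.38 ± 0.20). Cell cycle inhibitors were higher in 2 of 14 (median 0.57, adjusted p = 0.0345, adjusted p = 0.501 with an estimated correlation and 0.0658 without day 6 replicate 1), with Cdkn2a at 2.37 ± 0.10. Glycolysis genes were higher in 1 of 12, Pfkp (1.75 ± 0.16), with a median of 0.34 (adjusted p = 0.0224, adjusted p = 0.501 with an estimated correlation, 0.0502 without day 6 replicate 1 and 0.242 without neural stem cell replicate 1, where the median was 0.21, against 0.55 without replicate 2). None of the 29 cell cycle genes was called by limma, at a median of 0.09 (camera adjusted p = 0.676). Median and mean differed in sign for fibroblast and interferon genes. Counts adjusted over the list alone were equal to those over all genes. The neural stem cell arrays differed from each other in a few markers of other cells. Hbb-y, an embryonic globin, stood at 10.68 and 8.13, and Ttr, made by the choroid plexus, at 8.06 and 5.78. Ttr was no longer called against day 6 cells without neural stem cell replicate 1 (-0.58, against -1.72 with it).

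Astrocyte iPSCs were compared with day 6 cells to see what still separated the sorted cells from established pluripotent cells. Several pluripotency genes were far higher in the iPSCs than in the day 6 cells. Tdgf1, a co-receptor of Nodal, rose by 5.66 ± 0.13 from 6.16 ± 0.12 (SD, n = 3) to 11.83 ± 0.20 (n = 2), Dppa5a by 5.32 ± 0.15, Utf1 by 4.96 ± 0.19 and Zfp42 (Rex1) by 4.81 ± 0.15. Pou5f1 rose by 4.47 ± 0.17 and Sox2 by 2.07 ± 0.08. The largest adjusted p of these 6 genes was 1.1e-08. In total 656 genes were higher and 562 lower in the iPSCs, 1218 together.

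Of 30 pluripotency genes, 25 rose and 0 fell, by a median of 2.09 (adjusted p = 2.82e-27), and this call held with an estimated correlation (adjusted p = 0.0474). The delivered factors, 3 of 4 higher, also held (median 1.78, adjusted p = 2.16e-05, and adjusted p = 0.0474 with an estimated correlation). Epithelial genes rose in 11 of 19 (median 1.3, adjusted p = 6.1e-10, and adjusted p = 0.108 with an estimated correlation), led by Cldn6, a tight junction protein (4.14 ± 0.09). DNA methylation and Polycomb genes rose in 8 of 17 and fell in 2 (median 0.73, adjusted p = 7.15e-05, and adjusted p = 0.181 with an estimated correlation), and the de novo methylation genes Dnmt3l (4.18 ± 0.09) and Dnmt3b (3.77 ± 0.09) were the highest. Germline and 2-cell genes rose in 6 of 11 (median 1.05, adjusted p = 9.29e-07, and adjusted p = 0.108 with an estimated correlation), such as Tdrd12, a factor of transposon silencing (4.11 ± 0.08), and Sycp3, a meiotic chromosome protein (2.85 ± 0.15). Genes of other germ layers rose in 7 of 19 (median 0.54, adjusted p = 1.47e-05, and adjusted p = 0.181 with an estimated correlation), and imprinted genes in 6 of 16 (median 0.76, adjusted p = 0.000354, and adjusted p = 0.151 with an estimated correlation). Meg3, a maternally expressed RNA, rose by 3.14 ± 0.26. Cholesterol synthesis passed with 0 of 14 members called (median 0.39, adjusted p = 0.0007, and adjusted p = 0.181 with an estimated correlation).

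Fibroblast and feeder genes rose in 12 of 18 with 0 lower (median 1.58, adjusted p = 1.03e-09, and adjusted p = 0.181 with an estimated correlation), and the iPSCs were grown on fibroblast feeders. Dcn, a collagen-binding proteoglycan, rose by 4.46 ± 0.43, Lum by 3.22 ± 0.26 and Mmp2, a matrix protease, by 2.53 ± 0.32. The mesenchymal and matrix list, which shares 7 of its members with this one, had 11 of 26 higher and 2 lower (median 0.79, adjusted p = 0.000205, and adjusted p = 0.444 with an estimated correlation), with a median of 0.46 without astrocyte iPSC replicate 2. Of its 19 other members, 5 were higher and 2 lower, a count added after seeing the data. Endothelial and pericyte genes rose in 5 of 16 (median 0.06, adjusted p = 0.0295, adjusted p = 0.365 with an estimated correlation and 0.0574 without day 6 replicate 1), and the median ran from 0.01 to 0.10 without 1 array. The members that rose most were Eng (1.96 ± 0.09), a TGF-beta co-receptor, and Anpep (1.93 ± 0.10), a surface peptidase, both also made by other cells. Reactive genes rose in 3 of 17 and fell in 1 (median 0.47, adjusted p = 0.00605, adjusted p = 0.398 with an estimated correlation, 0.0594 without dim genes and 0.0711 without astrocyte iPSC replicate 2, where the median was 0.26).

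Neural stem and progenitor genes were lower in 8 of 28 and higher in 1 (median -0.33, adjusted p = 0.00375, and adjusted p = 0.281 with an estimated correlation). Pax6, a transcription factor of radial glia and the eye field, fell by 2.90 ± 0.11 from 8.51 ± 0.06 (n = 3) in day 6 cells, against 8.86 ± 0.17 (n = 3) in astrocytes. Insm1 and Sox11, factors of newborn neurons, fell by 2.0 ± 0.19 and 1.68 ± 0.15. Astrocyte genes did not pass (2 higher and 5 lower of 27, adjusted p = 0.059), though the glial factors Nfib and Nfia fell by 3.65 ± 0.14 and 2.99 ± 0.08. The sex check was lower in 3 of 4 members (median -1.41, adjusted p = 0.00271, and adjusted p = 0.181 with an estimated correlation). Adjusted over the list alone, 0 of 20 microglia genes were called, against 1 over all genes (Lyz2, 1.01 ± 0.33, adjusted p = 0.037, and not called without any 1 of 5 arrays, at 0.40 without astrocyte iPSC replicate 2), and the counts of all other lists were equal. Lyz2 was also lost with arrays centred on the median (0.99), with the replicate block (adjusted p = 0.0727) and with the added batch term (adjusted p = 0.0518). Median and mean differed in sign for cell cycle inhibitors, Hox, FGF and LIF genes.

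**Figure D2:**
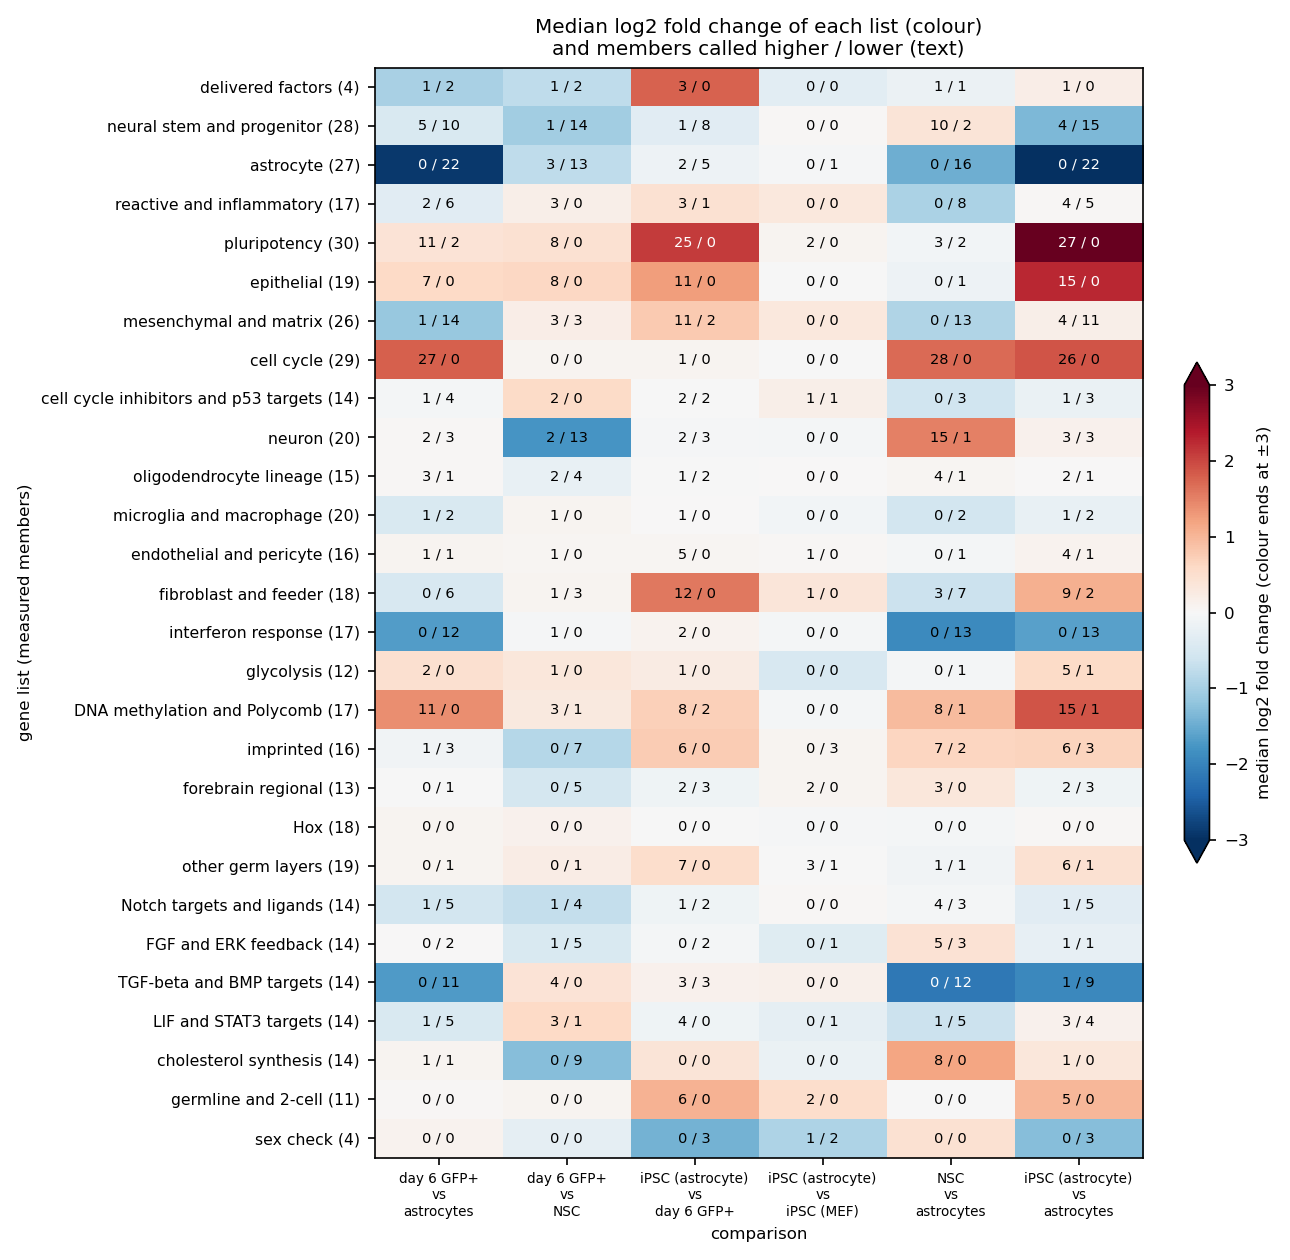
Colour shows the median log2 fold change of each of 28 gene lists (vertical axis, measured members in brackets) in each of 6 comparisons (horizontal axis), and each cell gives the members called higher and lower. Astrocyte genes are at -2.90 in day 6 cells against astrocytes, and pluripotency genes at 2.09 in astrocyte iPSCs against day 6 cells.

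The 2 iPSC groups were compared to see whether iPSCs of astrocyte origin differ from a line of fibroblast origin. They differed in 148 genes, 92 higher and 56 lower in astrocyte iPSCs, and in 216 when 16 was subtracted before log2, an alternative added after seeing the data. Pou5f1 and Sox2 were level, at -0.01 ± 0.19 and 0.08 ± 0.09, neither called. Cubn, an endocytic receptor of visceral endoderm and kidney, was lower (-4.34 ± 0.11, adjusted p = 1.2e-08), with Tcf15, a basic helix-loop-helix factor (-2.65 ± 0.08), and Srgn, a proteoglycan core (-2.26 ± 0.14). Tdrd12 (3.04 ± 0.09) and Cer1, a secreted Nodal antagonist (2.69 ± 0.12), were higher. Dab2, an endocytic adaptor, was lower on its brightest probe set (-2.23 ± 0.12) and level on its other one (-0.02).

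Germline and 2-cell genes were higher in 2 of 11 (median 0.53, adjusted p = 1.89e-07, and adjusted p = 0.234 with an estimated correlation). Pluripotency genes did not pass (2 higher of 30, adjusted p = 0.0825), while Zfp42 (1.96 ± 0.16) and Fbxo15 (1.20 ± 0.14) were higher. Glycolysis genes passed as lower with 0 of 12 called (median -0.47, adjusted p = 3.75e-05, and adjusted p = 0.525 with an estimated correlation). LIF and STAT3 targets were lower in 1 of 14, Gbx2 (-1.58 ± 0.09), with a median of -0.27 (adjusted p = 0.000259, and adjusted p = 0.234 with an estimated correlation). FGF and ERK feedback genes were lower in 1 of 14, Etv4 (median -0.36, adjusted p = 0.00033, and adjusted p = 0.525 with an estimated correlation). Etv4 stood at -1.01 ± 0.14 and was not called without astrocyte iPSC replicate 2 (-0.81) or MEF iPSC replicate 1 (-0.98). Cholesterol synthesis passed as lower with 0 of 14 called (median -0.19, adjusted p = 0.00333, and adjusted p = 0.525 with an estimated correlation). Imprinted genes were lower in 3 of 16 and did not pass (adjusted p = 0.783), with Nnat at -2.04 ± 0.18 and Grb10 at -1.90 ± 0.14, and their median and mean differed in sign, as did those of epithelial, oligodendrocyte and other germ layer genes.

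Fibroblast and feeder genes were higher in 1 of 18, Lum (1.99 ± 0.29), with a median of 0.36 (adjusted p = 0.00033, adjusted p = 0.571 with an estimated correlation and 0.347 without astrocyte iPSC replicate 2). That median was 0.06 without astrocyte iPSC replicate 2 and 0.73 without replicate 1. Mesenchymal and matrix genes had 0 of 26 called and a median of 0.32 (adjusted p = 0.00968, and adjusted p = 0.762 with an estimated correlation). Without astrocyte iPSC replicate 2 the median was -7.98e-05 (adjusted p = 0.692), without replicate 1 it was 0.62, and without MEF iPSC replicate 2 the adjusted p was 0.128. Reactive genes had 0 of 17 called (median 0.33, adjusted p = 0.0018, adjusted p = 0.525 with an estimated correlation and 0.262 without astrocyte iPSC replicate 2, where the median was 0.10). Astrocyte genes had 1 of 27 lower, Aldoc (-1.13 ± 0.16), with a median of -0.04 (adjusted p = 0.0105, adjusted p = 0.525 with an estimated correlation, 0.0832 without astrocyte iPSC replicate 1 and 0.0775 without MEF iPSC replicate 2). Without 1 iPSC array this median ran from -0.15 to -0.01. Aldoc was not called without astrocyte iPSC replicate 2 (-0.98).

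Sex-linked genes separated the 2 iPSC groups. Xist, the RNA of the inactive X chromosome, was higher in astrocyte iPSCs (2.69 ± 0.28), at 8.53 ± 0.12 (SD, n = 2) against 5.84 ± 0.14 (n = 2). The Y-linked Eif2s3y and Uty were lower (-2.83 ± 0.30 and -1.88 ± 0.23), and the list did not pass as a set that moves one way (1 higher and 2 lower of 4, adjusted p = 0.247). Astrocytes, day 6 cells and neural stem cells carried both Xist (9.86, 9.84 and 9.92) and Eif2s3y (6.90, 7.35 and 7.72). Origin, reporter, line and these sex-linked levels go together in this comparison. The sex of each line would rest on such RNA levels alone and is not established. Counts adjusted over the list alone were equal to those over all genes.

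Neural stem cells and astrocytes served as the neural references. Neural stem cells had 1293 genes higher and 1614 lower, 2907 in all, while over all probe sets 1951 were higher and 1816 lower. Dcx (3.95 ± 0.23), Nnat (4.67 ± 0.17) and Sox11 (3.30 ± 0.15) were higher, and Gfap (-6.20 ± 0.13), Aqp4, the water channel of astrocyte endfeet (-4.71 ± 0.07), and Apoe, a lipid carrier (-3.84 ± 0.14), were lower, the largest adjusted p of the 6 being 9.7e-08. Sox2 was not called, at -0.19 ± 0.08. Cell cycle genes were higher in 28 of 29 (median 1.69, adjusted p = 2.51e-16, and adjusted p = 0.212 with an estimated correlation). Neuronal genes were higher in 15 of 20 and lower in 1 (median 1.52, adjusted p = 4.81e-09, and adjusted p = 0.162 with an estimated correlation). Cholesterol synthesis was higher in 8 of 14 (median 1.18, adjusted p = 2.7e-08, and adjusted p = 0.0904 with an estimated correlation). Neural stem and progenitor genes were higher in 10 of 28 and lower in 2 (median 0.39, adjusted p = 0.00857, and adjusted p = 0.325 with an estimated correlation), and DNA methylation and Polycomb genes were higher in 8 of 17 and lower in 1 (median 0.94, adjusted p = 3.15e-05, and adjusted p = 0.162 with an estimated correlation).

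Astrocyte genes were lower in 16 of 27 (median -1.46, adjusted p = 3.97e-09, and adjusted p = 0.0904 with an estimated correlation), TGF-beta and BMP targets in 12 of 14 (median -2.15, adjusted p = 2.86e-08, and adjusted p = 0.0904 with an estimated correlation) and interferon response genes in 13 of 17 (median -1.92, adjusted p = 1.36e-07, and adjusted p = 0.162 with an estimated correlation). Reactive genes were lower in 8 of 17 (median -0.96, adjusted p = 2.78e-06, and adjusted p = 0.162 with an estimated correlation) and mesenchymal genes in 13 of 26 (median -0.89, adjusted p = 1.56e-05, and adjusted p = 0.365 with an estimated correlation). Microglia genes were lower in 2 of 20 (median -0.54, adjusted p = 0.00155, and adjusted p = 0.461 with an estimated correlation), cell cycle inhibitors in 3 of 14 (median -0.59, adjusted p = 0.00122, and adjusted p = 0.302 with an estimated correlation), and LIF and STAT3 targets in 5 of 14 with 1 higher (median -0.65, adjusted p = 0.00171, and adjusted p = 0.162 with an estimated correlation). FGF and ERK feedback genes were higher in 5 of 14 and lower in 3 (median 0.42, adjusted p = 0.0255, and adjusted p = 0.565 with an estimated correlation). This call was lost without dim genes (0.104), with cyclic loess (0.110), without astrocytes replicate 3 (0.0691) and without neural stem cell replicate 1 (0.0919). Forebrain regional genes were higher in 3 of 13 (median 0.33, adjusted p = 0.0401, and adjusted p = 0.302 with an estimated correlation), lost without dim genes (0.196), without astrocytes replicate 1 (0.0569) and without neural stem cell replicate 1 (0.0919). Fibroblast genes did not pass (3 higher and 7 lower of 18, or 3 and 8 adjusted over the list alone), and the other lists had equal counts. Median and mean differed in sign for Notch and germline genes.

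Astrocyte iPSCs against astrocytes, the end against the start of reprogramming, gave 1882 genes higher and 2272 lower, 4154 in all, while over all probe sets 2737 were higher and 2729 lower. Pou5f1 (6.33 ± 0.17) and Tdgf1 (6.16 ± 0.13) were higher and Fabp7 (-6.61 ± 0.14) and Gfap (-6.16 ± 0.13) lower, the largest adjusted p of the 4 being 1.8e-10. Pluripotency genes rose in 27 of 30 (median 3.34, adjusted p = 1.07e-17, and adjusted p = 0.0872 with an estimated correlation), epithelial genes in 15 of 19 (median 2.26, adjusted p = 5.1e-10, and adjusted p = 0.0872 with an estimated correlation), cell cycle genes in 26 of 29 (median 1.88, adjusted p = 3.96e-13, and adjusted p = 0.310 with an estimated correlation), and DNA methylation and Polycomb genes in 15 of 17 with 1 lower (median 1.89, adjusted p = 1.82e-08, and adjusted p = 0.0872 with an estimated correlation). Germline genes rose in 5 of 11 (median 0.99, adjusted p = 0.000289, and adjusted p = 0.269 with an estimated correlation) and genes of other germ layers in 6 of 19 with 1 lower (median 0.45, adjusted p = 0.0084, and adjusted p = 0.495 with an estimated correlation). Astrocyte genes fell in 22 of 27 (median -3.85, adjusted p = 1.16e-14, and adjusted p = 0.0752 with an estimated correlation), interferon genes in 13 of 17 (median -1.63, adjusted p = 5.54e-05, and adjusted p = 0.292 with an estimated correlation), neural stem and progenitor genes in 15 of 28 with 4 higher (median -1.34, adjusted p = 0.00232, and adjusted p = 0.310 with an estimated correlation), and TGF-beta and BMP targets in 9 of 14 with 1 higher (median -1.94, adjusted p = 0.00866, and adjusted p = 0.292 with an estimated correlation). Fibroblast and feeder genes were higher in 9 of 18 and lower in 2 (median 1.07, adjusted p = 0.0486, and adjusted p = 0.639 with an estimated correlation). Their call was lost without dim genes (0.147) and without each of 5 arrays, namely astrocytes replicates 1 (0.0501) and 2 (0.0586), day 6 replicates 1 (0.0540) and 2 (0.0526) and astrocyte iPSC replicate 2 (0.122). Reactive, mesenchymal, neuronal, oligodendrocyte and LIF genes did not pass and had a median and a mean of different sign. Counts adjusted over the list alone were equal to those over all genes.

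Some genes set the day 6 cells apart from each of the 4 other groups, 108 of them higher and 44 lower, 152 in all. These rest on 1 more comparison, day 6 cells against MEF iPSCs (585 genes higher and 634 lower, 1219 in all), whose gene lists were not tested. Foxd1 was higher than in any other group by at least 5.21 on the log2 scale, Tgm3, an epidermal transglutaminase, by at least 4.10, and Akr1c18, a steroid dehydrogenase, by at least 4.02. Gpr50, an orphan receptor, was higher by at least 3.53, Mal, a membrane protein of myelin and epithelia, by at least 3.41, and Necab1, a calcium-binding protein, by at least 3.31. Among lower genes, the extracellular matrix protein Tnc stood at 5.99 in day 6 cells and between 9.44 and 11.43 in the other group means, and Plpp3, a lipid phosphatase, at 6.48 against 9.06 to 11.89. Igfbp2, a binding protein of insulin-like growth factors, stood at 7.87 against 10.20 to 13.02. Rimklb, Akap12 and Fam171b completed the lowest 6, at 5.56, 8.34 and 7.19 in day 6 cells.

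The last question is where the day 6 cells lay between the references. Of the 2907 genes that differed between neural stem cells and astrocytes, 88.9% lay toward neural stem cells in day 6 cells, 63.7% were called in that direction and 1.89% in the other, and the median ratio of the 2 differences was 0.88. Of the 4154 genes that differed between astrocyte iPSCs and astrocytes, 96.0% lay toward the iPSCs, 64.5% were called in that direction and 0.313% in the other, with a median ratio of 0.82. Per day 6 array, the first share ran from 87.2% to 89.2% and the second from 95.1% to 96.0%. By cross-fit the shares were 88.2% and 95.2% and the median ratios 0.84 and 0.79. These genes are not independent replicates, so no p is given.

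Across genes, the fold changes of day 6 cells and of neural stem cells against astrocytes had a Pearson r of 0.696 and a Spearman rho of 0.616. Unchanged groups simulated against the same astrocyte arrays gave r = 0.447, with a covariance of 0.00594 against 0.482 observed, and cross-fit gave r = 0.678. With astrocyte iPSCs the r was 0.834 and rho 0.787, against a simulated 0.447, with a covariance of 0.709 against 0.00595 and a cross-fit r of 0.817. Day 6 cells and neural stem cells shared 634 genes called higher than in astrocytes, where independent lists would share 87.3, and 1217 called lower, against 163. Day 6 cells and astrocyte iPSCs shared 1018 higher, against 127, and 1661 lower, against 229.5. Part of these overlaps may come from the shared astrocyte arrays.

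**Figure D3:**
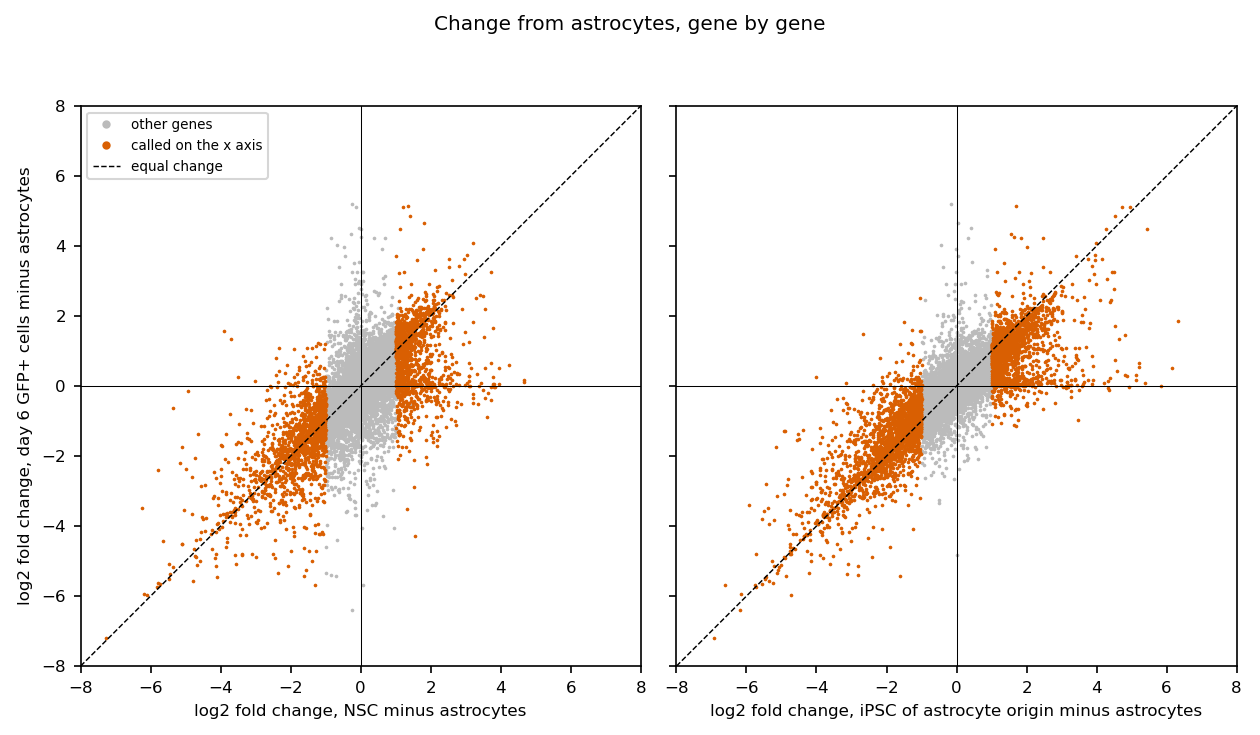
Each point is 1 of 19938 genes, with the log2 fold change of day 6 cells against astrocytes on the vertical axis and that of neural stem cells (left) or astrocyte iPSCs (right) on the horizontal axis, genes called on the horizontal axis in orange, and the dashed line at equal change. The r across genes is 0.696 on the left and 0.834 on the right.

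The genes called in neural stem cells against astrocytes differed by whether iPSCs shared the change, a division added after seeing the data. For the 1887 genes called in the same direction in astrocyte iPSCs, the median ratio in day 6 cells was 1.02 and 86.1% were called toward neural stem cells. For the 1020 genes not called in that direction in iPSCs, the median ratio was 0.29 and 22.2% were called, with 617 genes higher in neural stem cells at 0.08 and 403 lower at 0.63. Between neural stem cells and astrocyte iPSCs directly, with no astrocyte array involved, day 6 cells lay nearer neural stem cells for 41.5% of 2500 genes. The share was 26.7% for the 1498 genes higher in neural stem cells and 63.6% for the 1002 lower ones. A gene high in iPSCs alone counts as nearer neural stem cells here, whatever its level in astrocytes. Likewise, a gene high in neural stem cells alone counts as nearer iPSCs. Neither share by itself therefore measures likeness to the nearer group.

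**Figure D4:**
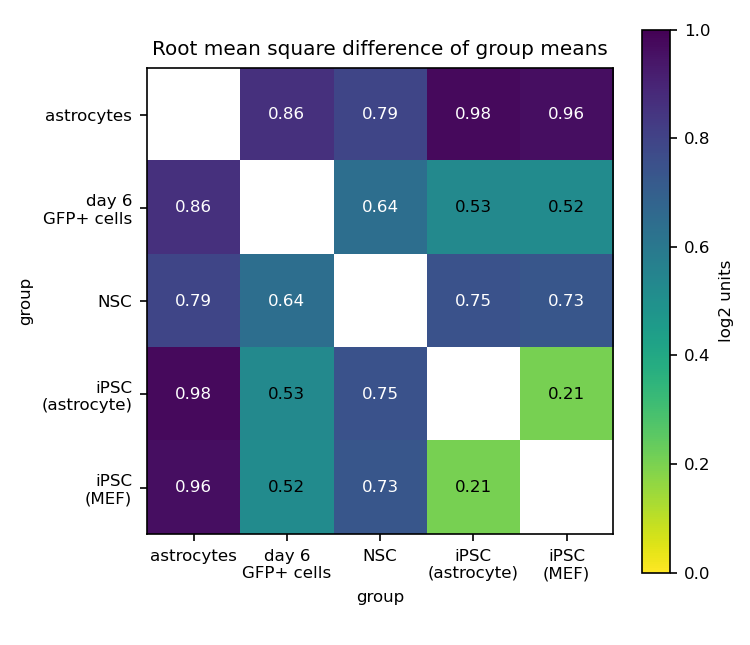
Root mean square log2 difference between the means of each pair of the 5 groups, with the part due to the spread between arrays subtracted. Day 6 cells lie 0.53 from astrocyte iPSCs, 0.64 from neural stem cells and 0.86 from astrocytes.

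By the root mean square difference over all genes, day 6 cells lay 0.86 from astrocytes, 0.64 from neural stem cells, 0.53 from astrocyte iPSCs and 0.52 from MEF iPSCs in log2 units. Neural stem cells lay 0.79 from astrocytes and 0.75 from astrocyte iPSCs, and the 2 iPSC groups lay 0.21 apart. Leaving out any 1 array gave 0.63 to 0.66 for the distance to neural stem cells and 0.51 to 0.54 for that to astrocyte iPSCs, so the order of these 2 was kept.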

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

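Tests chosen after the result was seen are the keratinocyte test with its marker list, the division of neural stem cell genes by their change in iPSCs with its split by direction, the cross-fit bound on the shared astrocyte arrays, and the count of feeder genes called in MEF iPSCs.

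Probe sets outside the main measurement also changed. Of 7064 probe sets with no gene name or with several, 663 were called by limma between day 6 cells and astrocytes, 385 higher and 278 lower. These probe sets have no gene in the comparisons above, and no explanation for them was tested.

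Genes that separate neural stem cells from astrocytes lay mostly toward neural stem cells in day 6 cells, and 2 explanations were weighed. Shared astrocyte arrays are argued against as the whole cause, since the median ratio stayed at 0.840 by cross-fit. Changes shared with iPSCs may account for much of it, but for genes not called in the same direction in iPSCs the median ratio was 0.293, between the bounds set for and against. For the 354 genes higher in neural stem cells whose iPSC and astrocyte means differ by under 0.5 on the log2 scale, the ratio was 0.049995 (0.0230 to 0.0754 over the day 6 arrays, quartiles -0.0645 and 0.326), with 26 genes called toward neural stem cells and 9 away, so most of these genes moved little and a few did move. For the 154 lower ones it was 0.519 (0.489 to 0.557, and 0.491 by cross-fit), on both sides of the bound of 0.5, so that part stays open, and the requirement that each array pass the bound was added after that value was seen.

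For the genes set apart in day 6 cells, such as Foxd1 and Tgm3, carried-over keratinocytes, considered because Tgm3 is epidermal and removed by the GFP sort only if they lack GFP, are argued against by 14 measured keratinocyte markers with a median log2 difference from astrocytes of 0.153 (quartiles 0.110 and 0.423). Of these, 2 were called, Krtdap and Lgals7, and the abundant keratins Krt5 and Krt14 stood at 6.38 and 6.36, against 6.25 and 5.91 in astrocytes. Sfn (0.84), Krt14 (0.45) and Sbsn (0.34) were higher under the fold limit, with a largest limma adjusted p of 0.0020. The marker list holds none of Sprr2b, Pkp1, Itgb4 and Perp, which were also set apart. It therefore argues only against cells rich in its own markers. A lone array is argued against by 152 genes as the lowest count without 1 day 6 array. Dim probe sets stay open, since the median level of 9.26 of the higher genes (lower quartile 8.19, against an upper quartile of 8.30 over all genes) is raised by their choice as higher in these cells, and the filter on dim genes, which left 151 set apart, can be passed by the day 6 arrays alone. A state of the day 6 cells of their own remains a hypothesis. So do the embryonic stem cell medium after infection, the viruses and selection by the sort, which the design does not separate.

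Of 18 fibroblast and feeder genes, 12 were called higher in astrocyte iPSCs than in day 6 cells and 9 in MEF iPSCs, where 1 was lower (Prrx1), and MEF feeder RNA is a candidate source. A shared source keeps its genes in 1 ratio, and over 15 members the SD of the log2 ratio of the excess between the iPSC groups was 0.7998, between the bounds set for and against it, with ratios from 0.884 (Twist2) to 6.83 (Lum). Members needed an excess of at least 50 intensity units in astrocyte iPSCs only. In MEF iPSCs the excess was 36.9 for Lum, 20.9 for Dpt and 45.7 for Mfap5. Part of the SD may therefore come from small denominators, and the bounds cannot decide. Of 19 other members of the mesenchymal list, 57.9% had a higher mean in both iPSC groups, between the bounds, though only 5 were called higher in astrocyte iPSCs (2 lower) and 3 in MEF iPSCs (1 lower). The fibroblast and feeder list also shifted with single astrocyte iPSC arrays. Its median against MEF iPSCs was 0.06 without replicate 2 and 0.73 without replicate 1. For the mesenchymal list the 2 medians were -7.98e-05 and 0.62. Feeder carry-over that varies between samples would give such a shift, but this was not tested. These values do not separate the feeders from the iPSCs' own transcription, because feeder preparations may differ between the lines.

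For day 6 cells against astrocytes, the 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05 (1 of 10 gave as many genes). The real split called 3360 genes and the highest other 0. Every other split puts both cell types on each side, which widens the spread within sides. Its low count therefore adds no evidence.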

How the results depend on the processing

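Tests chosen after seeing the data are the subtraction of 16 before log2 and the batch term for replicate 1 arrays. The 6 counts of called genes and the genes set apart stayed within 1.5 times under every alternative run for them (the fit of only the 2 groups compared was not run for genes set apart) but the removal of the fold limit, which by construction raised them to 9755 (day 6 cells against astrocytes), 7655 (against neural stem cells), 5896 (astrocyte iPSCs against day 6 cells), 1150 (astrocyte against MEF iPSCs), 9144 (neural stem cells against astrocytes), 10173 (astrocyte iPSCs against astrocytes) and 1061 (set apart). For the shifts below, the cause was not tested. Distances without dim genes average over 12592 genes in place of 19938, so they cannot be set directly against the full values. Cyclic loess gave shares of 87.3% toward neural stem cells and 95.2% toward iPSCs. Leaving out dim genes gave correlations of 0.702 (neural stem cells) and 0.837 (iPSCs) and distances from day 6 cells of 1.08 (astrocytes), 0.793 (neural stem cells), 0.655 (astrocyte iPSCs) and 0.643 (MEF iPSCs). Cross-fit gave correlations of 0.678 and 0.817 and an iPSC share of 95.2%, and subtracting 16 gave correlations of 0.683 and 0.825.

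Leaving out 1 array at a time, the lowest and highest counts were 3327 and 3409, 1683 and 1897, 1190 and 1322, 135 and 176, 2860 and 3002, and 4018 and 4309 in the order above, and 145 and 159 for genes set apart. The neural stem cell share ran from 87.6% to 90.0% and its correlation from 0.675 to 0.704, the iPSC share from 95.7% to 96.1% and its correlation from 0.829 to 0.837. Distances ran from 0.858 to 0.865, 0.626 to 0.664, 0.513 to 0.543 and 0.507 to 0.519. Where this left 1 array in a group, it was assumed to vary like the others. The mesenchymal list between the iPSC groups had its lowest median, -7.98e-05, without astrocyte iPSC replicate 2 and its highest, 0.624, without replicate 1.

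With the replicate block the counts were 3364, 1797, 1247, 150, 2900 and 4164, and 149 set apart, and no list call was lost. Arrays with the same number shared deviations with r from -0.0969 to 0.410 (11 of 21 pairs over 0.1), against -0.408 to 0.321 for arrays with different numbers (4 of 36 over 0.1). In groups of 2 arrays the deviations mirror each other, so these pairs are not independent. Pairing was to be assumed only if every same-numbered pair passed 0.1, so the replicate numbers were not used as pairs in the reported values, and whether samples were paired stays open. The rule covered all groups and cannot decide for astrocytes and day 6 cells alone. Their same-numbered pairs had r of 0.410, -0.0080 and 0.224 for replicates 1, 2 and 3. Replicate 1 of each also shared deviations with MEF iPSC replicate 1, at r of 0.396 for astrocytes and 0.408 for day 6 cells. The 0.410 is therefore not particular to these 2 groups. An effect common to replicate 1 arrays cannot be told apart from pairing here. Among 726 gene results followed, the block ended 2 calls (Lyz2 in astrocyte iPSCs against day 6 cells, adjusted p = 0.0727, and Dusp4 in astrocyte iPSCs against astrocytes, at 0.90) and added 5, cyclic loess ended 10 and added 6, and leaving out arrays ended 52 and added 40 over all fits, with 0 reversed. Of 76 list calls, 74 were lost with an estimated correlation, 8 without dim genes and 3 with cyclic loess. Signal near the lowest intensity of 20.2 limits what dim genes can show.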

Other observations

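Sex-linked genes gave an order of arrays that the group means hide. Xist stood at 9.99, 9.39 and 10.22 in astrocytes replicates 1, 2 and 3, and at 9.91, 9.38 and 10.23 in day 6 replicates 1, 2 and 3. Eif2s3y stood at 7.43, 6.76 and 6.5 in the astrocytes and at 7.68, 7.5 and 6.86 in the day 6 cells of the same numbers. In MEF iPSCs, Kdm5d, also Y-linked, stood at 5.19 while Eif2s3y stood at 8.48, and in neural stem cells the 2 genes stood at 6.54 and 7.72.

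The neurofilament genes Nefl and Ina, picked after their values were seen, did not move together. Nefl stood at 11.75 ± 0.08 (SD, n = 3) in day 6 cells, 6.61 ± 0.22 (n = 3) in astrocytes and 7.96 ± 0.10 (n = 2) in neural stem cells, whereas Ina, another neurofilament gene, stood at 6.51 ± 0.11 in day 6 cells and 10.24 ± 0.58 in neural stem cells. Stmn2, a microtubule regulator of neurons, was bright in all 5 groups, with means from 10.72 in astrocyte iPSCs to 12.44 in astrocytes. Bgn, a matrix proteoglycan, stood at 10.98 in astrocytes, 6.16 in day 6 cells, 7.39 in neural stem cells, 11 in astrocyte iPSCs and 10.93 in MEF iPSCs.

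None of the tests below was planned, and the values were chosen after they were seen. A first hypothesis is that same-numbered astrocyte and day 6 samples came from the same litters, which the order of Xist raises. Genotypes of X-linked and Y-linked sequence in the stored RNA would test it, and if they match, a fit with pairs would be the right one for this comparison. Another is that each astrocyte, day 6 and neural stem cell sample pooled cells of both sexes, which single-cell counts of Xist and Eif2s3y would test. The last concerns Foxd1 and Nefl, which were higher in day 6 cells than in astrocytes and astrocyte iPSCs. Foxd1 stood at 11.08 in day 6 cells and 5.72 in astrocyte iPSCs, and a time course of GFP-positive and GFP-negative cells after infection would show whether such genes mark cells on the way to iPSCs or cells that stop.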
